A study of Homo sapiens with 4 samples.

How the data were processed

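RNA was measured in 4 human testicular cell cultures, described in the labels as Leydig cells, Sertoli cells and a cell type abbreviated PMC, exposed to leptin at 0, 0.25, 1 or 10 ng/ml. Each dose has 1 library. The 4 library titles share 1 identifier code, and they do not state whether it stands for a donor, a batch or a culture. The deposited table holds raw read counts per gene for 57783 Ensembl gene identifiers, and per the submitters' processing notes reads were trimmed with Trim Galore and aligned with STAR to the human build hg19. Tool versions, the counting program, its strand setting and the annotation release are not given in the sources used here. Whether reads from overlapping or antisense genes were separated is therefore unknown, and such genes are uncertain.

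Gene symbols were taken by identifier from GENCODE release 29, which is built on a later genome build, so no coordinates are printed. Of the identifiers, 52301 had a symbol and 5482 had none, and the unnamed ones held 0.534 to 0.612% of each library's counts. No mitochondrially encoded gene was among the named identifiers, so that list was not analysed here. Y-linked genes and XIST were kept in library totals and left out of every result. All 4 count columns were used.

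Total counts were 39443518, 38638343, 31991547 and 34081118 at 0, 0.25, 1 and 10 ng/ml. A floor of 3 counts corresponds to 0.0761, 0.0776, 0.0938 and 0.088 CPM in these libraries. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

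Counts were scaled with TMM factors in edgeR 4.0.16 (R 4.3.3), and log2 CPM was computed with a prior count of 2. With 1 library per dose no p-value was given for a pair of libraries. A gene was counted as apart when its log2 fold was at least 1 in size and the 95% exact Clopper-Pearson counting interval of the ratio excluded 1. This rule was applied to the 13742 genes with a mean of at least 1 CPM. The same count was made between leptin libraries, and with each of the 4 libraries set apart in turn. Genes strictly rising or falling with dose, and at least 2-fold apart between the ends, were counted and ranked among 12 orders of the libraries.

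Models across all 4 libraries used the edgeR quasi-likelihood test with filterByExpr and Benjamini-Hochberg adjustment at 0.05. The first fitted a linear trend on dose rank, and the second set the 3 leptin libraries against the untreated one. Each has 2 residual degrees of freedom. In the second, the untreated library is assumed to vary like the leptin libraries, whose own spread includes any dose effect. The TMM factors came from all genes, as for the pairs of libraries. That detail was not fixed before the data were examined: factors from the filtered genes were run first during exploration, and are given among the alternatives.

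Gene lists were fixed before the data were examined, except the list of 20 prostate and epithelial markers. A list's median log2 fold was set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. The resulting percentiles are printed for the hedgehog pathway, steroidogenesis, leptin receptor, inflammatory and ribosomal protein lists only. Genes were named by a rule fixed before the data were examined. For each dose it took the 10 largest rises and 10 largest falls with at least 50 reads in the higher library. It added the measured hedgehog, steroidogenesis and leptin receptor genes, the 4 members of each other list with the largest fold, the 5 smallest p-values per direction in each model, and the 5 largest changes per direction in dose order. List members under the filter, and prostate markers, are named outside that rule with their counts or ratios. Some genes that the rule names are not reported here.

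The steps were tested on simulated libraries with a dispersion of 0.01. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery below that level was not tested. For the comparison of 10 ng/ml with none, the rule of size recovered 93% of 100 genes changed 2.5-fold and 100% of 100 changed 4-fold among 13745 genes, and called 7 others. For the dose trend, 100% of 100 genes with a slope of 0.5 and of 100 with a slope of 0.7 log2 units per dose step were recovered among 17150, with 14 others. For leptin at any dose, 100% of 100 genes at 2.5-fold and of 100 at 4-fold were recovered among 17938, with 10 others. Slopes below 0.5 were not simulated, so recovery of the smaller slopes named below was not tested. The dispersion was chosen with no replicate to set it by. The other genes called are therefore not a rate of false calls for these cultures. Alternatives were DESeq2 1.42.0 and limma 3.58.1, other scalings, filters, prior counts, fold sizes and dose scales, and leaving out libraries. Thinning to the smallest library, removal of a smooth trend on GC content and exon length (mgcv 1.9.3), and leaving out genes that follow the epithelial profile were added after seeing the data.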

Results

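The series measured RNA in cultured human testicular cells exposed to leptin, a hormone that signals through the receptor LEPR, and its title concerns hedgehog signalling and Leydig cell function. There were 4 libraries, 1 each at 0, 0.25, 1 and 10 ng/ml, with 39443518, 38638343, 31991547 and 34081118 counts. No dose was replicated. Differences between 2 libraries therefore have no replicate check, and their 95% intervals cover counting error only.

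The first question was how each leptin library differed from the untreated one. The Wnt modulator gene SFRP4 (ENSG00000106483) was higher at every dose, with 6.29 CPM in the untreated library and 37.4, 44.2 and 49.8 CPM at 0.25, 1 and 10 ng/ml. Its ratio to the untreated library at 10 ng/ml was 7.91 (95% interval 6.92 to 9.08). The collagen genes COL16A1 (ENSG00000084636) and COL15A1 (ENSG00000204291) had ratios of 6.98 (5.87 to 8.33) and 5.58 (4.03 to 7.88) at 10 ng/ml. LAMP3 was 5.73 times its untreated level (4.97 to 6.63). The chemokine gene CXCL8 (ENSG00000169429) was lower, at 375, 188, 113 and 64.6 CPM over the 4 doses, a ratio of 0.172 (0.165 to 0.180) at 10 ng/ml. CSF3, which encodes a granulocyte growth factor, had a ratio of 0.183 (0.133 to 0.247), and the potassium channel subunit gene KCNAB1 one of 0.124 (0.0817 to 0.183). IGFBP5, which encodes an insulin-like growth factor binding protein, was at 3486 CPM without leptin and 854 CPM at 10 ng/ml.

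By the rule of size, 138 genes were higher and 103 lower at 0.25 ng/ml, 163 and 135 at 1 ng/ml, and 313 and 258 at 10 ng/ml, out of 13742. Which direction held more genes depended on the setting: at 1.5-fold there were 605 higher and 706 lower at 0.25 ng/ml and 655 and 694 at 1 ng/ml, and at 10 ng/ml there were 286 and 295 after thinning each library to the smallest total count. Of the 103 lower genes at 0.25 ng/ml, 80 had the profile of a group of prostate and epithelial markers that were also lower there. Without such genes 23 were left. That profile was a level below the untreated one at 0.25 and 10 ng/ml, and higher at 1 than at 0.25 ng/ml. Genes picked as lower at 0.25 ng/ml meet part of it by selection, and its share over all genes is not given. Having it therefore does not show where a gene's RNA came from. At 10 ng/ml 49 of the 258 lower genes had that profile. Between leptin libraries far fewer genes were apart: 46 higher and 5 lower at 1 against 0.25 ng/ml, 11 and 16 at 10 against 1 ng/ml, and 20 each way at 10 against 0.25 ng/ml. With scaling by total count only, the split at 10 against 1 ng/ml was 4 higher and 23 lower.

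**Figure D1:**
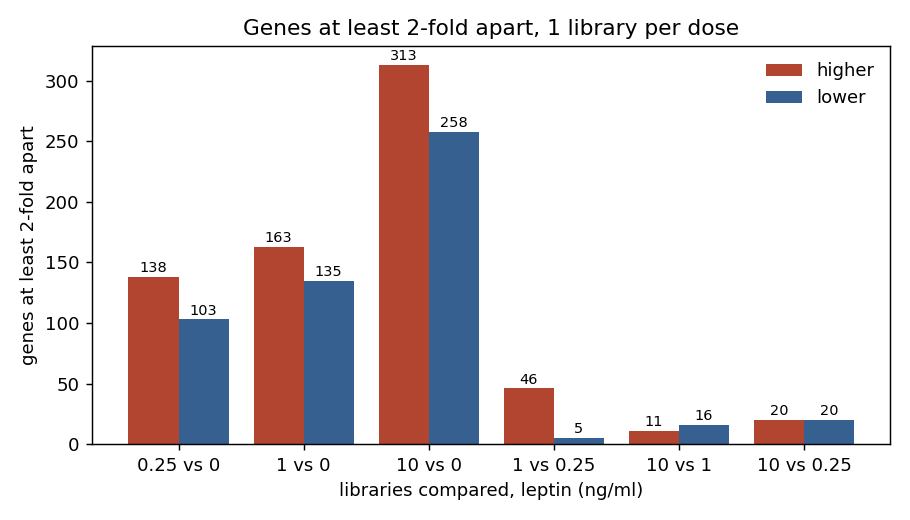
Bars give the number of genes at least 2-fold higher or lower (vertical axis) for each pair of libraries (horizontal axis, leptin in ng/ml), with 1 library per dose. The comparisons with the untreated library range from 241 to 571 genes in total, and those between leptin libraries from 27 to 51.

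The untreated library differed from all 3 leptin libraries on 1 side in 129 genes, 111 of them higher and 18 lower with leptin. The split was 60 and 0 at a mean of at least 5 CPM, 180 and 69 without a filter on low counts, and 445 and 240 at 1.5-fold. Setting apart the 0.25, 1 or 10 ng/ml library in the same way gave 1, 0 and 3 genes. In the edgeR quasi-likelihood test of leptin at any dose, 1042 genes were higher and 950 lower at an adjusted p below 0.05, out of 17902. SFRP4 was higher by 2.80 ± 0.19 (SE) on the log2 scale (edgeR adjusted p = 5.08e-45), and IGFBP5 fell by 1.51 ± 0.12 (edgeR adjusted p = 2.74e-35). GDF15, a stress-induced cytokine gene, was higher by 1.68 (edgeR adjusted p = 6.8e-27), and MT2A, a metallothionein gene, fell by 1.25 (edgeR adjusted p = 6.96e-20). DESeq2 gave 819 higher and 444 lower. These p-values rest on dispersion pooled across genes and do not measure spread between cultures of 1 dose. All of these genes were set against 1 untreated library, so the test cannot separate leptin from anything else particular to that culture.

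The overlap of the 3 comparisons is raised by the untreated library they share. At 1 and 10 ng/ml, 147 genes were higher and 96 lower in both, against 1.55 and 0.2 in simulated unchanged libraries and 3.71 and 2.54 for independent lists. Fewer lower genes were shared with 0.25 ng/ml: 114 genes were higher and 21 lower at both 0.25 and 1 ng/ml (simulated 1.5 and 0.4, independent 1.64 and 1.01), and 127 and 43 at both 0.25 and 10 ng/ml (simulated 1.85 and 0.25, independent 3.14 and 1.93). Across genes, which are not independent replicates, the folds at 1 and 10 ng/ml correlated at 0.860, against 0.485 in the simulation, and their covariance was 0.149 against 0.0270. The correlations were 0.817 at 0.25 and 1 ng/ml and 0.837 at 0.25 and 10 ng/ml, against 0.491 and 0.490, with covariances of 0.110 and 0.139 against 0.0271 for both. With 1 untreated library the control could not be divided. The simulated libraries were unchanged, with a median dispersion of 0.0073 and no replicate to set it by. Their overlap is therefore not that of lists as long as the real ones, and the figures for independent lists leave out the shared library. Neither shows what a shared library does to lists of this length. All of the excess may therefore come from a difference particular to the untreated culture.

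The design is also a dose series. In dose order and at least 2-fold apart between the ends, 176 genes were rising and 161 falling. The next highest of 12 orders, with 0.25 and 1 ng/ml exchanged, held 159 genes in all. No smallest size was asked of a single step, so the 2-fold difference can come from the first step alone. COL15A1 counts as rising at 1.14, 5.70, 6.28 and 6.37 CPM. The orders ranked 1 to 5 all began with the untreated library (337, 159, 78, 70 and 21 genes), so the ranking in part restates that library's distance. The balance turned with a trend on GC content and length removed, to 165 rising and 183 falling. CXCL8 had a slope of -0.84 ± 0.05 (SE) log2 units per dose step (edgeR adjusted p = 8.03e-12). IL33, VCAM1 and HMGA2, which encode an alarmin cytokine, an adhesion molecule and a chromatin protein, had slopes of -0.62, -0.62 and -0.60 (edgeR adjusted p = 2.08e-09, 1.29e-08 and 1.28e-08). The sulfotransferase gene SULT1E1 had a slope of -0.79 (edgeR adjusted p = 1.63e-06). CD14, DEPP1 and KRT7 had positive slopes of 0.55, 0.50 and 0.45, each with an edgeR adjusted p of 6.23e-06. The metabolic hormone gene FGF21 had 12, 30, 48 and 67 reads. The edgeR trend test on dose rank called 951 higher and 813 lower genes out of 17050. Before adjustment, 4206 of the 17050 had a p under 0.05. With so many, adjusting over a short list alone passes more members of many lists. Counts adjusted over a list alone, given below, therefore do not single out a pathway. The trend depended on the dose scale: with dose in ng/ml edgeR called 0 genes, with 1267 at an unadjusted p under 0.05, and limma also called 0. With log2(dose + 0.25) edgeR called 2 higher and 26 lower. Leaving out a library also moved the balance, to 157 higher and 402 lower without the untreated library and 112 and 238 without the 10 ng/ml library, against 1876 and 1372 without 0.25 ng/ml and 430 and 344 without 1 ng/ml.

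Hedgehog signalling is named in the title. GLI1 (ENSG00000111087), a transcription factor and readout of the pathway, had ratios to the untreated library of 1.08 (0.760 to 1.55), 0.843 (0.565 to 1.25) and 1.22 (0.851 to 1.74) at 0.25, 1 and 10 ng/ml, so no difference was detectable at this depth. The receptor gene PTCH1 (ENSG00000185920) had ratios of 0.762 (0.606 to 0.956), 0.785 (0.620 to 0.992) and 0.682 (0.532 to 0.870), under 2-fold at each dose. HHIP, which encodes a hedgehog-binding protein, was the 1 member past the rule of size, at 0.420 (0.242 to 0.701) at 10 ng/ml, and its trend did not pass (edgeR adjusted p = 0.0849). BOC, a co-receptor gene, fell with dose rank (edgeR adjusted p = 0.0143). KIF7 passed the trend narrowly in the positive direction (edgeR adjusted p = 0.0386) but not with DESeq2 (adjusted p = 0.0668), limma (0.0519) or edgeR with TMM factors from the filtered genes (0.0512). Without the untreated library neither BOC nor KIF7 passed (edgeR adjusted p = 0.53 and 0.204), nor without the 1 ng/ml library (0.0828 and 0.0578), and KIF7 did not pass without the 10 ng/ml library (0.666). Over all genes tested, 1 of the 18 measured members was higher and 1 lower in the trend, and 6 passed when adjusted over the list alone. The list's median log2 fold was -0.09, -0.26 and -0.04, at percentiles 12.8, 0.38 and 29.7 of matched random lists. The ligand genes DHH, IHH and SHH had at most 17 reads in any library. In the list of hedgehog target genes, medians were 0.02, -0.24 and -0.09 (mean -0.08 at 0.25 ng/ml, opposite in sign), and 1 of 13 measured members rose and 2 fell in the trend, with 4 passing when adjusted over the list alone. FOXF1 and CCND1 fell (edgeR adjusted p = 0.00102 and 0.00271), but did not pass without the untreated library (edgeR adjusted p = 0.324 and 0.333), nor CCND1 without the 10 ng/ml library (0.13). BCL2, an inhibitor of cell death, had a ratio of 2.21 (1.54 to 3.21) at 10 ng/ml and passed the trend narrowly (edgeR adjusted p = 0.0481). It did not pass with DESeq2 (adjusted p = 0.153), edgeR with DESeq2 size factors (0.0601) or edgeR with TMM factors from the filtered genes (0.0626), nor without the 0, 1 or 10 ng/ml library (edgeR adjusted p = 0.533, 0.127 and 0.359).

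For Leydig cell function, STAR (ENSG00000147465), which carries cholesterol into mitochondria for steroid synthesis, stood at 262, 261, 235 and 264 CPM, with ratios of 0.995, 0.895 and 1.005 at 0.25, 1 and 10 ng/ml. CYP11A1, the enzyme that makes pregnenolone, had a ratio of 1.52 (1.27 to 1.81) at 10 ng/ml, and its trend did not pass (edgeR adjusted p = 0.0761). The steroidogenic transcription factor gene NR5A1, the electron transfer gene FDXR and the lipoprotein receptor gene SCARB1 rose with dose rank, by 0.16, 0.19 and 0.17 log2 units per step (edgeR adjusted p = 0.0338, 0.015 and 0.0268). These 3 calls held under the 5 other tools, scalings and filters, and were lost without the 0, 1 or 10 ng/ml library (edgeR adjusted p of NR5A1 0.471, 0.0941 and 0.286, of FDXR 0.301, 0.0581 and 0.174, and of SCARB1 0.146, 0.061 and 0.48). HSD11B1, which interconverts cortisone and cortisol, fell from 123 to 38.2 CPM (edgeR adjusted p = 3.12e-08), and passed without each of the 4 libraries in turn. Such refits have 1 residual degree of freedom and rest on dispersion pooled across genes. In all, 3 of 14 measured members were higher and 1 lower in the trend, and 7 passed when adjusted over the list alone. The list's medians were 0.08, 0.09 and 0.26, at percentiles 69.3, 89.1 and 98.0, but its mean at 1 ng/ml was -0.02, opposite in sign to the median. At 10 ng/ml its mean was 0.07, and its median 0.14 with a trend on GC content and length removed. CYP17A1 and LHCGR had at most 2 reads in any library.

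**Figure D2:**
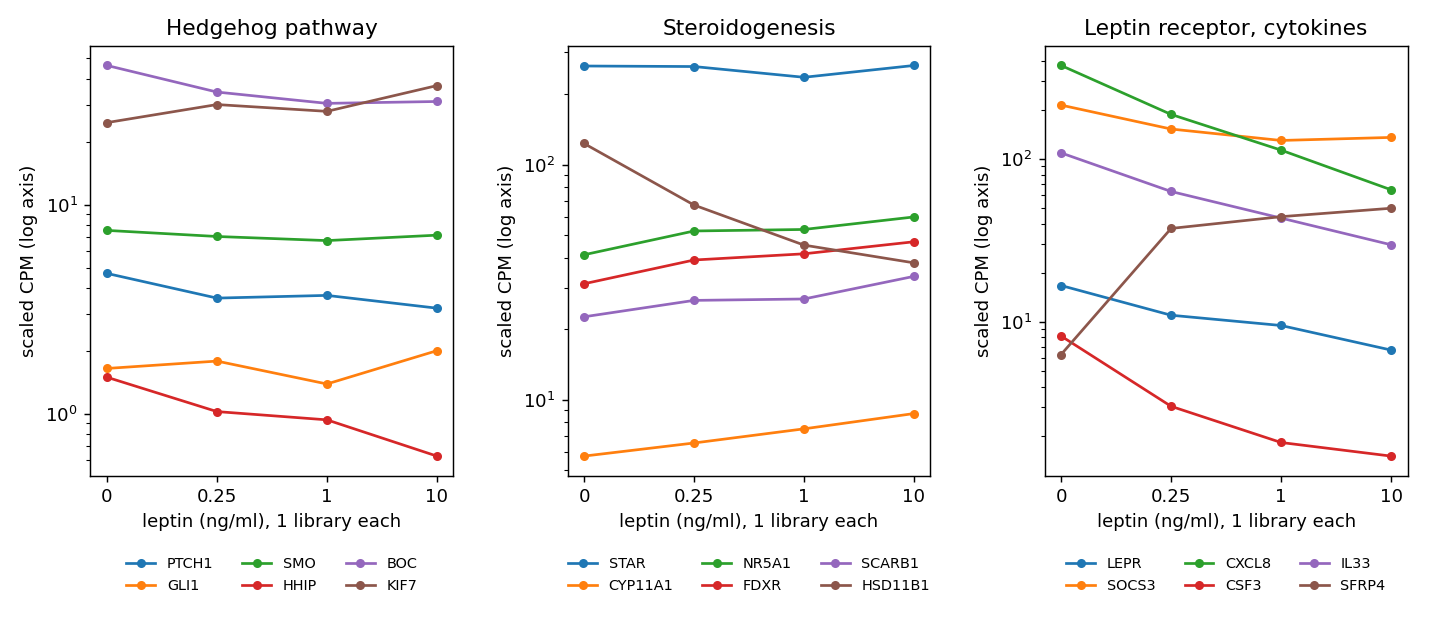
Points give scaled CPM on a log axis against leptin dose in ng/ml, 1 library each, for named genes in 3 panels. STAR stays between 235 and 264 CPM, while HSD11B1 goes from 123 to 38.2 CPM and CXCL8 from 375 to 64.6 CPM.

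In the leptin receptor and JAK-STAT list, LEPR (ENSG00000116678) fell with dose rank, at 16.69, 10.96, 9.48 and 6.70 CPM (slope -0.42 ± 0.07, SE; edgeR adjusted p = 8.95e-05). The feedback inhibitor genes SOCS2 and SOCS3 also fell (edgeR adjusted p = 9.61e-05 and 0.00611), and MTOR rose (edgeR adjusted p = 0.0141). LEPR and SOCS2 passed without each of the 4 libraries in turn, in refits with 1 residual degree of freedom and dispersion pooled across genes. Without the untreated library SOCS3 and MTOR did not pass (edgeR adjusted p = 0.362 and 0.297), nor SOCS3 without the 1 ng/ml library (0.066) or MTOR without the 10 ng/ml library (0.346). Of 20 measured members 1 was higher and 3 lower in the trend, and 11 passed when adjusted over the list alone. The list's medians were -0.04, -0.19 and -0.12, at percentiles 5.26, 0.43 and 3.2 of matched random lists. LEP itself, under the filter of 1 CPM and so not among the 20, had 6, 17, 33 and 31 reads and rose in the trend (edgeR adjusted p = 0.012). It passed in 4 of 5 other tools, scalings and filters, with no adjusted p from DESeq2, and not without the 0 or 10 ng/ml library (edgeR adjusted p = 0.356 and 0.053). The STAT3 target genes had medians of -0.06, -0.13 and 0.00, with 1 member higher and 3 lower in the trend.

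Among inflammatory cytokines and NF-kB targets 7 of 17 measured genes fell in the trend, with CXCL8, CSF3, CXCL6 and CCL20 the 4 with the largest folds, and 3 rose. That list's medians were -0.27, -0.36 and -0.32, at percentiles 0.02, 0 and 0.06 of matched random lists. Interferon-stimulated genes had medians of 0.30, 0.45 and 0.58, and in the trend 6 of 15 rose, IRF7 among them (edgeR adjusted p = 9.26e-05), and 1 fell. IRF7 rose at each dose step. XAF1, also called, stood at 32.7 CPM without leptin and 57.6, 55.3 and 56.9 CPM with it, so its call rests on the untreated library. Refits without that library are not given for the lists in this paragraph. In the unfolded protein and amino acid stress list 5 of 14 rose and none fell, and the chaperone gene HSPA5 had a ratio of 2.04 (2.02 to 2.06) at 10 ng/ml. TGF-beta, activin and BMP response genes had medians of -0.32, -0.37 and -0.41, and 6 of 16 fell, including ID1. Matrix genes LUM and VCAN fell (edgeR adjusted p = 3.43e-06 and 3.86e-05), while the list's medians were 0.07, 0.03 and 0.07. Its means at 1 and 10 ng/ml were -0.09 and -0.04, opposite in sign.

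Cell cycle genes had medians of -0.67, -0.38 and -0.78. MKI67, a proliferation marker, had ratios of 0.482, 0.733 and 0.503. In the any-dose edgeR test 13 of 21 were lower at an adjusted p below 0.05, and 5 in the trend. Their counts were lowest at 0.25 and 10 ng/ml, as were those of the prostate and epithelial markers, whose medians were -0.78, -0.11 and -0.61.

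Of the cell type lists, Leydig stem or progenitor markers had medians of -0.26, -0.43 and -0.57, and 5 of 10 fell in the trend. PDGFRA, a receptor on mesenchymal cells, was at 752 CPM without leptin and 340 CPM at 10 ng/ml. Sertoli cell markers had medians of -0.75, -0.88 and -0.68, and 3 of 5 fell, SOX9 among them (edgeR adjusted p = 0.0216). Peritubular myoid and smooth muscle markers had medians of 0.25, 0.34 and 0.50. Of these 4 of 8 rose, with the actin gene ACTA2 at a ratio of 2.52 (2.46 to 2.59) at 10 ng/ml, and SMTN fell. Of 9 listed Leydig markers 3 were measured, STAR, CYP11A1 and NR5A1, with medians of 0.18, 0.36 and 0.53. All 3 are also members of the steroidogenesis list above, so these medians are not separate evidence. Epithelial markers had medians of -0.46, -0.02 and -0.51. No lymphocyte, mast cell or erythroid marker passed the filter, and 2 macrophage, 2 endothelial, 1 spermatid and 1 Schwann cell marker did.

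**Figure D3:**
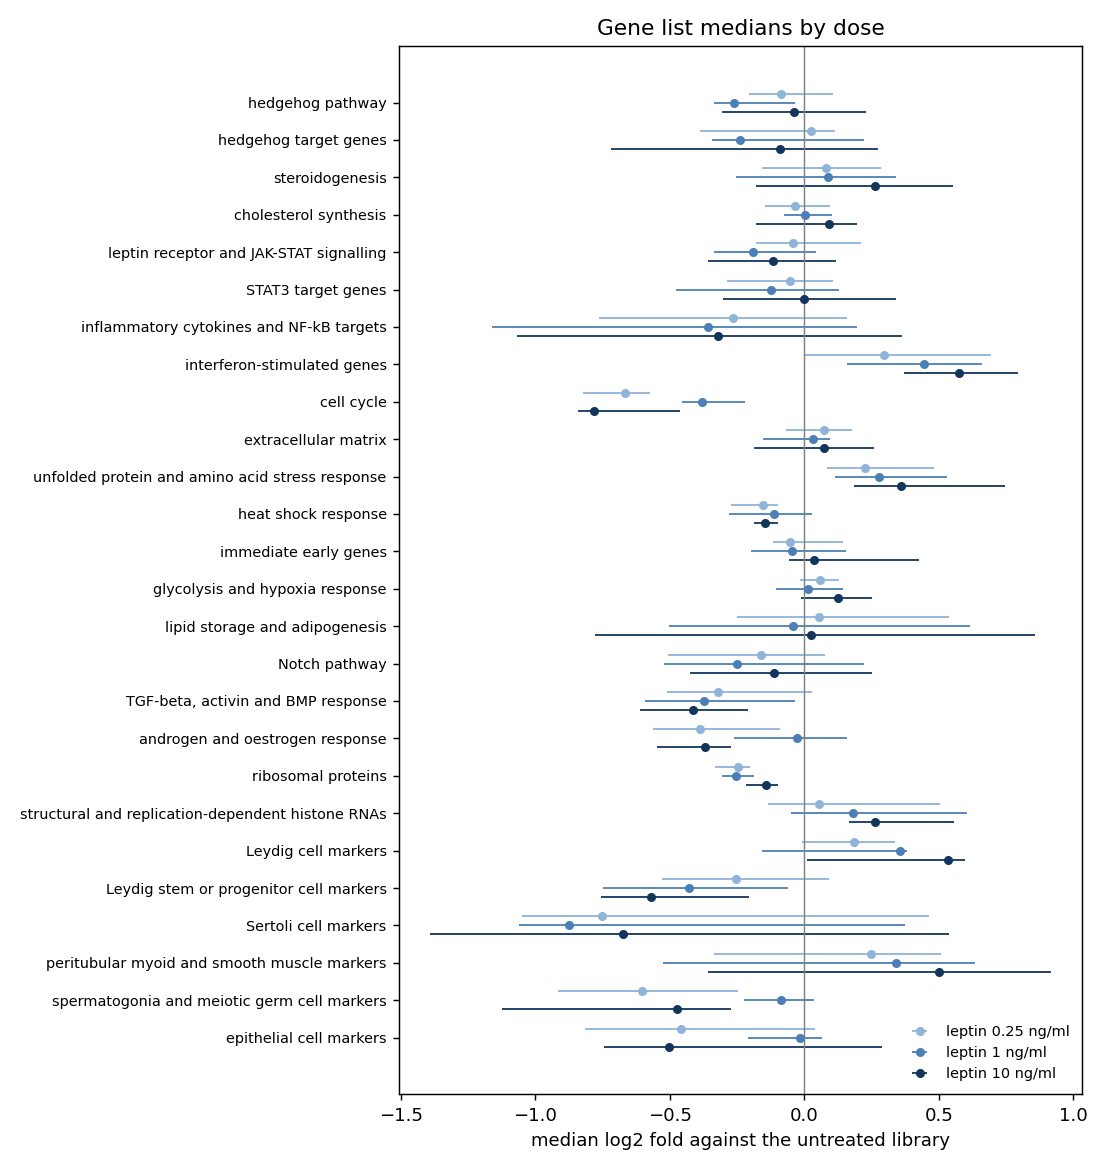
Points give the median log2 fold of each gene list's measured members against the untreated library (horizontal axis), 1 point per leptin dose, and bars are 95% bootstrap intervals over genes, which do not measure replicate error. Cell cycle medians lie at -0.67, -0.38 and -0.78 and interferon-stimulated genes at 0.30, 0.45 and 0.58.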

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

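The alternatives were chosen before the data were examined, except thinning, the GC and length trend, leaving out genes with the epithelial profile, and the TMM factors of filtered genes. Scaling by DESeq2 size factors or total count and a prior count of 0.5 kept each total within 1.5 times, but not each direction: by total count only, 4 genes in place of 11 were higher at 10 against 1 ng/ml, and by either scaling 3 in place of 5 were lower at 1 against 0.25 ng/ml. Without a filter on low counts, genes at least 2-fold apart from the untreated library numbered 886, 875 and 1359 at 0.25, 1 and 10 ng/ml, with a mean of at least 5 CPM 84, 133 and 276, and at 1.5-fold 1311, 1349 and 2263. At 0.25 ng/ml the balance turned to lower genes without a filter (350 higher, 536 lower) and at 1.5-fold (605 and 706), and was 67 and 17 at 5 CPM. At 1 ng/ml it was 434 and 441, 655 and 694, and 79 and 54 under these 3. At 10 ng/ml it was 286 and 295 after thinning and 268 and 272 after removing the GC and length trend. Between leptin libraries (1 against 0.25, 10 against 1, 10 against 0.25 ng/ml) the counts were 440, 338 and 337 without a filter, 5, 1 and 5 at 5 CPM, and 370, 341 and 337 at 1.5-fold. Genes apart from all 3 leptin libraries numbered 249, 60 and 685, and genes in dose order 951, 191 and 1077, under the same 3 settings. A looser filter or fold counts more genes by construction. Without genes of the epithelial profile 161, 298 and 522 were left, a setting that by construction removes lower genes.

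The dose trend gave 1402 genes by DESeq2, 1713 by limma and 1531 with TMM factors from the filtered genes, 1512 of them shared with the 1764. With dose in ng/ml it gave 0 and with log2(dose + 0.25) 28. On both scales the step from 0 to 0.25 ng/ml is the smallest in dose. Yet it held the most genes at least 2-fold apart, 241, against 51 from 0.25 to 1 and 27 from 1 to 10 ng/ml. A straight line on such a scale cannot follow so large a first step. Whether this was the whole cause was not tested. Leaving out 1 library gave 350 (without 10 ng/ml) to 3248 genes (without 0.25 ng/ml), with 1 residual degree of freedom. Leptin at any dose gave 1263 genes by DESeq2, 1158 of them shared with the 1992, for a cause not tested, and 2118 with TMM factors from the filtered genes. Leaving out a leptin library gave 1332 to 2222 genes, and leaving out the untreated one leaves no comparison. Medians of the hedgehog and steroidogenesis lists stayed within their bootstrap intervals, but at 10 ng/ml steroidogenesis went from 0.26 (-0.18 to 0.55) to 0.14 and hedgehog from -0.04 (-0.31 to 0.23) to -0.13 with the GC and length trend removed, and no named gene or list past its threshold reversed. Depth limits DHH, IHH, CYP17A1 and LHCGR, with at most 4 reads in any library.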

Other observations

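The tests of chance order, depth, GC content and length, epithelial and outside RNA, dose order of the markers, and the cell cycle genes were chosen after the patterns were seen, with only the bounds for depth and for GC content and length set before their values were computed. Cholesterol synthesis genes had medians of -0.03, 0.00 and 0.09, with LSS among the genes rising and SQLE falling in the edgeR trend (adjusted p = 0.0408 and 0.0468). Immediate early genes had medians of -0.05, -0.05 and 0.04, with 7 of 22 rising and 2 falling, and their means of 0.08, 0.04 and 0.19 were opposite in sign at the lower 2 doses. Lipid storage genes had medians of 0.05, -0.04 and 0.03, with PLIN2 and G0S2 rising and ANGPTL4 and PDK4 falling. Notch genes had medians of -0.16, -0.25 and -0.11. Medians were -0.16, -0.11 and -0.15 for heat shock genes, and 0.06, 0.02 and 0.12 for glycolysis and hypoxia. Ribosomal protein genes had medians of -0.25, -0.26 and -0.14, with 29, 28 and 24 of 29 below 0. Their percentiles were 0, 0.02 and 1.52, so a low percentile is not particular to the hedgehog list. Androgen and oestrogen response genes had medians of -0.39, -0.03 and -0.37, the 4 measured germ cell markers -0.60, -0.09 and -0.48, and the 3 measured structural and histone RNAs 0.05, 0.18 and 0.26.

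The first pattern was the distance of the untreated library and the order of the others by dose. Too few splits exist for chance to be judged: 1 of the 12 orders gave as many trend genes as the 1764 found (highest other 982), 1 of the 12 gave as many genes in dose order as the 337 found (highest other 159), and 1 of the 4 ways of setting a library apart gave as many as the 1992 found (highest other 0 by edgeR, where up to 879 genes had an unadjusted p under 0.05, and 0 by limma). Depth and GC content or gene length bias are argued against as whole causes of the count of 571 at 10 ng/ml. It was 581 after thinning to the smallest library and 540 after removing the trend. The split went from 313 higher and 258 lower to 268 and 272 without the trend, and whether the same genes remained was not compared. Fold had a Spearman correlation with GC content of -0.15, -0.05 and 0.25 at 0.25, 1 and 10 ng/ml. A part from GC content is therefore not excluded. Genes lower at 10 ng/ml had a median log2 ratio of -0.26 (95% bootstrap interval -0.31 to -0.22) between the 1 and 0.25 ng/ml libraries, opposite to the epithelial genes, which argues against less epithelial RNA as their whole cause. A culture or library difference that coincides with the dose cannot be told apart from leptin with 1 library per dose.

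The second pattern was that 20 prostate and epithelial markers, listed after their levels were seen, varied together out of dose order. Their summed level was 0.551, 0.956 and 0.663 of the untreated one, they took 0.0184% of counts without leptin, and the most abundant, SPINK1, was at 59.6, 29.8, 56.3 and 39.6 CPM. The median log2 ratio of the 20 was -0.80 (95% bootstrap interval over genes -0.98 to -0.71) at 0.25 ng/ml against none. At 1 against 0.25 ng/ml it was 0.89 (0.57 to 1.01). This is not the course of a response in dose order, but the list was drawn up after that course was seen. The values therefore restate the pattern and are no separate test of such a response. A candidate explanation is 1 outside source of RNA, but chi-square per degree of freedom was 1.93 for 1 ratio between the libraries, above counting error (chi-square p = 3.13e-05) and below each of 1000 random lists (median 6.24). The bound was first set at 2, which this value meets, and was tightened to counting error after the value was seen, so that stays open. Because the markers were listed after their levels were seen, a chi-square below that of random lists does not decide it either. The list includes KLK3, TMPRSS2, EPCAM and CDH1, which other lists also hold, and no tissue other than testis is named in the labels.

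The third pattern was the lower cell cycle genes. Of their loss at 0.25 ng/ml a share of 0.513 was also seen at 1 ng/ml, against 0.0761 for the prostate and epithelial markers, a difference of 0.437 (95% bootstrap interval 0.259 to 0.618). The cell cycle genes thus did not keep the ratios of these markers. The markers were listed after their levels were seen, so their share was open to that choice. The difference therefore does not decide whether less RNA from that source was the whole cause. Less RNA from it may add to the values at 0.25 and 10 ng/ml. In these libraries the fall was not in dose order. Of the 21 genes 0 lay in strict dose order, and the median of -0.67 at 0.25 ng/ml (95% bootstrap interval over genes -0.82 to -0.58) was below that of -0.38 at 1 ng/ml (-0.45 to -0.22). These intervals do not measure spread between cultures. With 1 library per dose, fewer dividing cells in dose order with 1 deviant culture is therefore not excluded. Less RNA from the source of the markers and fewer dividing cells in dose order, acting together, were not tested. Fewer dividing cells with leptin, without a dose order, was not separated from a difference of the untreated culture.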
